A study of Homo sapiens with 4 samples.

How the data were processed

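RNA was sequenced from MV4;11, an established human acute myeloid leukaemia cell line, after 24 h with vehicle (2 libraries) or with CU-T12-9 at 1 µg/mL (2 libraries). CU-T12-9 is a small-molecule agonist of the TLR1/TLR2 receptor pair. Per the labels' protocols, total RNA was extracted with a Zymo miniprep kit and libraries followed the usual Illumina procedure, and the series' design text speaks of mRNA profiles. Whether polyadenylated RNA was selected, and whether the libraries kept strand, is not given in the sources used here. The labels differ on the vehicle: the treatment protocol names PBS and the sample treatment label names DMSO. The vehicle libraries are called DMSO throughout, after the sample label.

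The authors deposited 1 table of whole-number read counts per gene symbol for the 4 libraries, with 56638 symbols and no summary rows. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, aligned with TopHat2 to GRCh37 and counted with featureCounts 1.5.2. The annotation, the handling of reads that map to several places and the strand setting are not given in the sources used here. Rows of near-identical genes (HLA genes, histones, ribosomal proteins, the CCL3 and CCL4 copies, NCF1 and ferritin pseudogenes) and of overlapping or antisense genes are therefore uncertain, since reads can be split or moved between them. The table holds no coordinates and the reference at hand was of another build, so no positions are given. Gene symbols are those of the table. CXCL8 and TIGAR stand in it as IL8 and C12orf5, matched through RefSeq synonyms, and 12205 of the 14018 tested symbols were found in the reference annotation.

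Library totals were 25867733 and 23892934 reads for DMSO and 23201117 and 23087102 reads for CU-T12-9. A single read corresponded to 0.0384 to 0.0442 CPM, the read count scaled to the TMM-adjusted library size, and a floor of 3 reads to 0.115 to 0.133 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Log2 CPM correlated across genes at 0.996 between the DMSO libraries and 0.994 between the CU-T12-9 libraries, and at 0.927 to 0.929 between groups. A chi-square per degree of freedom of 2.42 for the DMSO pair and 7.03 for the CU-T12-9 pair, over genes with at least 20 reads, put both pairs beyond sampling noise, so all 4 libraries were counted as separate samples. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

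Counts were analysed in R 4.3.3. The gene comparison used the quasi-likelihood F-test of edgeR 4.0.16 with group as the only term, the default expression filter (filterByExpr, 14018 genes kept), TMM normalisation and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 5.0%. Standard errors of log2 fold changes are the fold change divided by the square root of F. Means and SDs are of CPM from TMM-adjusted library sizes (reads in tested genes) over the 2 libraries of a group. A fold against a group with no reads is a lower bound, computed against a floor of 3 reads over both libraries of the group. For 1 to 3 reads in a group the ratio of counts, each per TMM-adjusted library size, is given with an exact 95% interval. Medians of the lists compared by camera did not move when such genes were set to their bound. The calling step was tested on simulated data for this comparison, with 14018 genes of which 50 were changed at each fold size. It recovered 26% of the genes changed 1.2-fold, 68% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, with 9 false calls among 149. The simulation changed far fewer genes than the data and gave both groups the same spread, so these rates need not hold here.

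The test, the 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says that a choice was made later. Each list with at least 5 tested members (22 lists) was compared with all other tested genes by camera of edgeR and limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and fry, which asks only whether the members of a list move on balance one way, were alternatives. The first of these takes its p-value from the residual degrees of freedom, 2 here. Its p-values are therefore far larger than with the preset, even for lists with a low estimated correlation. The lists were Toll-like receptors and proximal signalling, NF-kB targets, cytokines and chemokines, interferon response, monocyte and macrophage differentiation, granulocyte granules, stem cell and MLL-fusion genes, MYC and ribosome biogenesis, cell cycle, p53 targets, BCL2 family and caspases, antigen presentation, MAPK immediate early genes, FLT3 and STAT5 targets, unfolded protein and ATF4 stress, cholesterol synthesis, hypoxia and glycolysis, NRF2 and AHR response, lysosome and autophagy, markers of T and NK, B, erythroid, megakaryocyte and epithelial or fibroblast cells, mitochondrially encoded mRNAs, cytoplasmic ribosomal proteins and replication-dependent histones. Camera was also tested on simulated counts, where it called a raised set and 0 of 20 unchanged sets. The simulated genes varied independently of each other, so this did not test the effect of correlation between genes.

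The named genes were TLR1, TLR2, TLR6, CD14 and MYC in any case; the 10 largest rises and 10 largest falls in log2 fold change among genes past the threshold with a mean of at least 5 CPM and non-overlapping groups; and, for each list, up to 4 members past the threshold with the largest absolute log2 fold change, or the 2 with the smallest p if none passed. Clone names, LOC names, symbols ending in P and digits, antisense and LINC names and small RNA names were left out of the top 10. Read literally, this also left out NRP2, ARHGAP31, IGFBP2 and MIR146A. Other list members are named as examples of their list, and were chosen after their values were seen. A few genes that the rule takes are not reported here.

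The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, library totals alone, no filter on low counts, a filter of 1 CPM in at least 2 libraries, the replicate number of the titles as a block, leaving out each library in turn, a test against a fold of 1.2 (glmTreat) and an adjusted p threshold of 0.01. Thinning the libraries to the smallest total and a test against a fold of 2 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.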

Results

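Transcript counts were collected from MV4;11, a human acute myeloid leukaemia line with a KMT2A-AFF1 fusion and an internal tandem duplication of FLT3. The cells had been exposed for 24 h to CU-T12-9, a small-molecule TLR1/TLR2 agonist, at 1 µg/mL, or to vehicle. Each group held 2 libraries. The DMSO libraries held 25867733 and 23892934 counted reads and the CU-T12-9 libraries 23201117 and 23087102. Between 19568 and 20039 genes had at least 1 read in a library. The only comparison of the design is CU-T12-9 against DMSO, which asks how gene expression of this leukaemic line responds to a TLR1/2 agonist. Since the labels name both DMSO and PBS as the vehicle, a contribution of DMSO itself to the comparison could not be separated.

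In MV4;11 cells under CU-T12-9, all 24 NF-kB targets and 15 of 18 tested cytokines and chemokines (28 listed) rose. So did 29 of 31 tested interferon-response genes and 19 of 22 antigen presentation genes. All 31 cell cycle genes and all 28 genes of MYC and ribosome biogenesis fell. With an estimated correlation between genes the NF-kB and cell cycle lists kept their call (camera adjusted p = 0.0348 for each), and the others did not (adjusted p = 0.175, 0.322, 0.175 and 0.175 for cytokines, interferon response, antigen presentation and MYC). That setting rests on 2 residual degrees of freedom, so a call lost there need not be due to correlation. EBI3, a cytokine subunit, went from 0.141 ± 0.0367 CPM under DMSO to 171 ± 22.9 CPM under CU-T12-9 (SD, n = 2 in each group). BIRC3, an inhibitor of apoptosis induced by NF-kB, went from 0.159 ± 0.0471 to 61.9 ± 4.43 CPM, and the MHC class II gene HLA-DQA1 from 0.42 ± 0.00331 to 247 ± 17.4 CPM. RRM2, a subunit of ribonucleotide reductase, fell from 398 ± 5.64 to 68.7 ± 0.582 CPM, and the neutrophil elastase gene ELANE from 233 ± 1.54 to 33.5 ± 4.84 CPM.

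Of 14018 genes tested, 9135 changed (65.2%), 4483 being higher and 4652 lower in CU-T12-9 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Large changes were mostly rises. The fitted fold change was over 4 for 616 higher and 329 lower genes, and over 16 for 199 higher and 9 lower genes. Many of the calls were small changes: tested against a fold of 2, an alternative added after the data were seen, 1013 genes were higher and 778 lower. In 9134 of the 9135 changed genes both libraries of one group lay above both of the other, as did 49.1% of the genes that were not called, against 33.3% by chance.

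**Figure D1:**
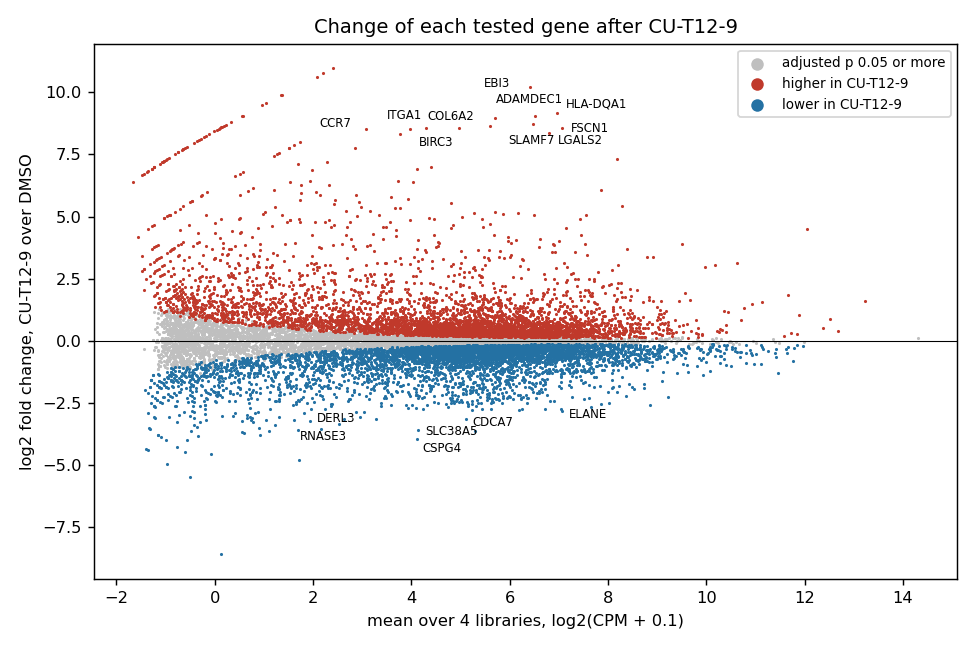
Log2 fold change (CU-T12-9 over DMSO) of each of the 14018 tested genes against its mean level over the 4 libraries, as log2(CPM + 0.1), with red and blue points for the 4483 higher and 4652 lower genes and grey points for genes that did not pass. The largest rises reach far above the largest falls, and the lines of points at the upper left are genes with no or very few DMSO reads, whose fitted change is not a bound.

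The 10 largest rises among genes with a mean of at least 5 CPM, with the names that the rule leaves out set aside, were EBI3, HLA-DQA1, ADAMDEC1, COL6A2, SLAMF7, FSCN1, BIRC3, ITGA1, CCR7 and LGALS2. The name rule left out NRP2 (0 and 478 reads, at least 173-fold higher), ARHGAP31 (log2 fold change 8.62) and MIR146A (8.51), which lie in the same range. Of the 10 genes kept by the rule EBI3 had the largest log2 fold change, 10.20 (SE 0.20, adjusted p = 1.23e-09 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FSCN1, an actin-bundling protein of mature dendritic cells, rose from 0.697 ± 0.1 to 267 ± 47.1 CPM. SLAMF7, a surface receptor of the SLAM family, rose from 0.42 ± 0.00331 to 178 ± 0.39 CPM, and ADAMDEC1, a metalloprotease of macrophages and dendritic cells, from 0.338 ± 0.0648 to 183 ± 6.32 CPM. COL6A2, a collagen VI chain, rose from 0.199 ± 0.0448 to 103 ± 9.07 CPM. The lymph node homing receptor CCR7 had 2 reads over both DMSO libraries and 769 over both CU-T12-9 libraries, a ratio of 418 (95% interval 115 to 3456). HLA-DQA1 can share reads with the similar HLA-DQA2, and its level is uncertain to that extent.

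Under the same rule the 10 largest falls were in CSPG4, SLC38A5, RNASE3, CDCA7, CPNE7, CTNNAL1, KCNK5, DERL3, ELANE and PRSS57. IGFBP2, left out by its name, fell 12.4-fold, and the clone-named RP11-84C10.2 fell 8.7-fold. These genes outside the rule were chosen after their values were seen. CSPG4, which encodes the NG2 proteoglycan found on KMT2A-rearranged blasts, fell 15.6-fold, from 32.3 ± 1.9 to 2.07 ± 0.448 CPM (log2 fold change -3.96, SE 0.14, adjusted p = 2.02e-08 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The glutamine transporter gene SLC38A5 fell 11.9-fold, and CDCA7, a MYC target expressed in cycling cells, 8.82-fold. RNASE3, ELANE and PRSS57 encode proteins of myeloid granules, and fell 10.1-fold, 6.97-fold and 6.88-fold.

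Member counts of the lists below are over all genes tested, and the count adjusted over the list alone was the same except where it is given. Of the 22 lists compared with the other genes, 10 were higher and 4 lower in CU-T12-9 with a preset correlation. With an estimated correlation, 2 kept their call, the NF-kB targets and the cell cycle list. The estimates for these 2 lists, -0.00613 and -0.0148, lay below the preset value of 0.01. Their larger p-values in that setting thus came from its 2 residual degrees of freedom. For the other lists the tests do not separate the 2 sources.

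TLR1 and TLR2, the receptor pair at which CU-T12-9 acts, were both expressed under DMSO and rose. TLR1 went from 5.61 ± 0.164 to 18 ± 1.99 CPM (log2 fold change 1.68, SE 0.12, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 2.38e-06). TLR2 went from 120 ± 3.46 to 192 ± 12.3 CPM (0.68, SE 0.06, adjusted p = 8.57e-06 by the same edgeR test). TLR6, the other partner of TLR2, rose from 2.79 ± 0.23 to 7.03 ± 0.943 CPM, and TLR10 7.79-fold from 0.399 ± 0.0328 CPM. The co-receptor gene CD14 had 1 and 1 reads under DMSO and 8 and 9 under CU-T12-9, too few to be tested. The kinase gene IRAK2 rose 4.21-fold, while IRAK1 fell (log2 fold change -0.99). In all, 10 of 16 tested members of the receptor and proximal signalling list rose and 2 fell (11 and 2 adjusted over the list alone). The list was higher by camera (adjusted p = 0.042, and adjusted p = 0.335 with an estimated correlation), and its adjusted p was 0.0524 with a filter of 1 CPM.

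All 24 NF-kB targets and feedback genes rose, with a median log2 fold change of 3.37 (camera adjusted p = 5.42e-56, and 0.0348 with an estimated correlation). After BIRC3, the largest rises were in the co-stimulatory receptor gene CD40 (log2 fold change 6.91, SE 0.19), the atypical inhibitor NFKBIZ (5.13, SE 0.10) and the adhesion molecule ICAM1 (5.04, SE 0.08). ICAM1 went from 11.1 ± 1.35 to 366 ± 10.3 CPM. The feedback genes NFKBIA and TNFAIP3 rose by 3.47 and 4.25 on the log2 scale, and the non-canonical subunits RELB and NFKB2 by 4.10 and 3.85.

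Among cytokines and chemokines, 15 of 18 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 3.57 (camera adjusted p = 1.25e-13, and adjusted p = 0.175 with an estimated correlation). The other members of the 28 listed, IL6, CCL20 and CSF2 among them, had too few reads to be tested. A gene nearly unread under DMSO is tested only if it rises, so these counts favour rises. CXCL10 had no read under DMSO and 227 under CU-T12-9, at least 82.2-fold higher. CCL4 had 3 and 253 reads, a ratio of 91.6 (95% interval 31 to 447), and its level is uncertain because reads can be shared with near-identical copies. IL12B, a subunit of interleukin-12 and interleukin-23, had 2 and 136 reads, a ratio of 73.9 (95% interval 20.1 to 616). IL1B rose 19-fold, CXCL8 (listed as IL8) 15.7-fold and TNF 2.73-fold, while OSM fell 11.9-fold.

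Of 31 tested interferon-response genes, 29 rose and 1, HERC5, fell (log2 fold change -0.46), with a median of 2.56 (camera adjusted p = 1.53e-15, and adjusted p = 0.322 with an estimated correlation). The antiviral genes OAS3, IFI44L and MX1 rose 58.7-fold, 24.1-fold and 14.6-fold, and the guanylate-binding protein gene GBP2 15.3-fold. Antigen presentation genes rose in 19 of 22 cases and 1 fell, with a median log2 fold change of 1.77 (camera adjusted p = 4.66e-34, and adjusted p = 0.175 with an estimated correlation). The class II genes led: beside HLA-DQA1, HLA-DMB rose 37.4-fold, HLA-DPB1 29.8-fold and HLA-DPA1 23.2-fold. CIITA, the master regulator of class II transcription, rose by 3.91 on the log2 scale and the invariant chain CD74 by 3.15, against 1.15 for B2M, the light chain of class I molecules.

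All 31 cell cycle and DNA replication genes fell, with a median log2 fold change of -2.06 (camera adjusted p = 6.87e-62, and 0.0348 with an estimated correlation). The replication factors GINS2, CDC45 and CDC6 fell by 2.74, 2.73 and 2.72 on the log2 scale, and RRM2 by 2.53. MKI67 fell from 462 ± 13.2 to 133 ± 3.82 CPM. MYC fell from 471 ± 1.39 to 233 ± 1.2 CPM (log2 fold change -1.01, SE 0.05, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.33e-07). All 28 genes of the MYC and ribosome biogenesis list fell, with a median of -0.79 (camera adjusted p = 1.64e-11, and adjusted p = 0.175 with an estimated correlation). NOP16, NOP58, ODC1 and NOP56 fell most, by 1.25, 1.19, 1.16 and 1.16 on the log2 scale. Of 83 cytoplasmic ribosomal protein genes, 66 fell and 1 rose (68 and 1 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 5.94e-05, and adjusted p = 0.569 with an estimated correlation). The paralogs RPL39L and RPL22L1 fell most, 5.02-fold and 4.27-fold, ahead of RPL17 and RPL35 at 1.83-fold and 1.63-fold. Of 22 tested replication-dependent histone genes, 16 rose and 2 fell, with a median of 1.58 (camera adjusted p = 0.00136, and adjusted p = 0.335 with an estimated correlation). HIST2H2BE rose 12.3-fold to 17.3 ± 0.857 CPM. HIST1H3E and HIST1H3D rose from levels below 0.2 CPM, and HIST1H2AI from 3 to 28 reads, a ratio of 10.1 (95% interval 3.13 to 52.1). Histone rows are near-identical and uncertain one by one.

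**Figure D2:**
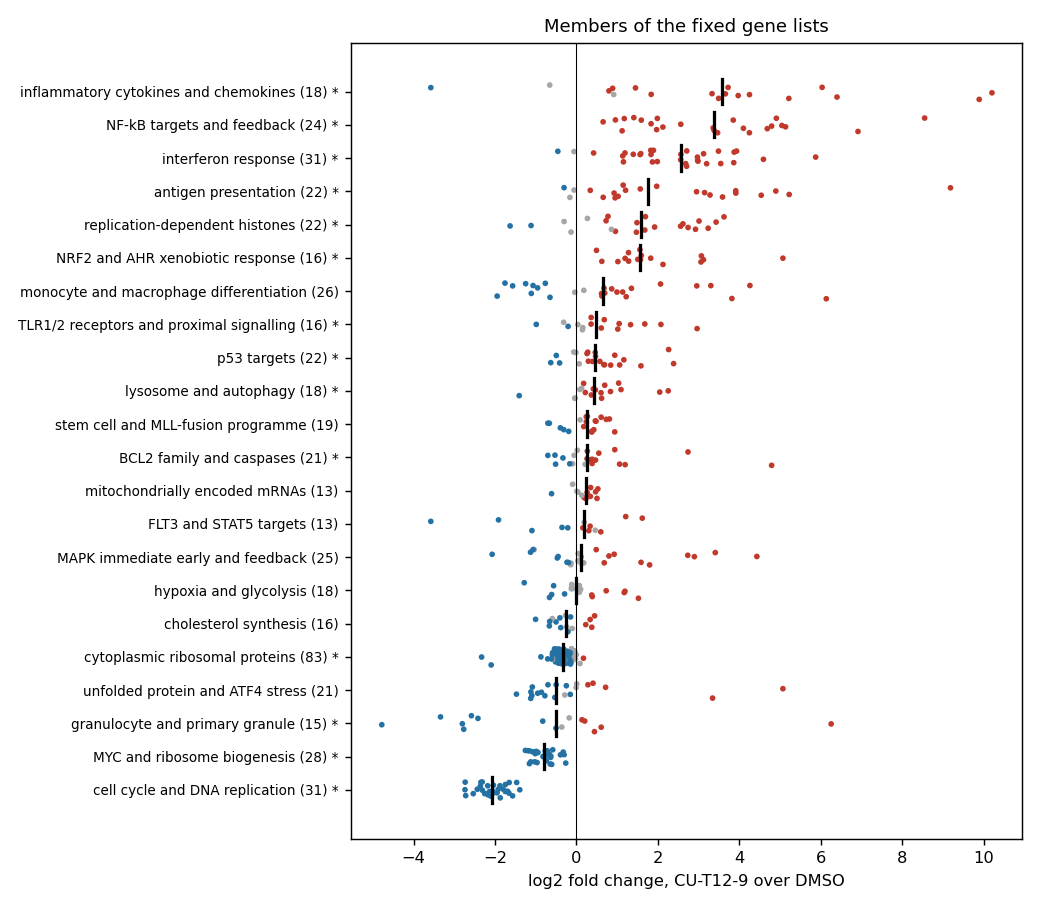
Log2 fold change (CU-T12-9 over DMSO) of each tested member of the 22 fixed gene lists with at least 5 tested members, with the number tested in parentheses. Red and blue points are higher and lower members, grey points did not pass, black bars are medians, and an asterisk marks the 14 lists called by camera with the preset correlation. The lists of cytokines and chemokines and of cell cycle genes stand at opposite ends, with medians of 3.57 and -2.06. NF-kB targets follow the cytokines, with a median of 3.37.

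Differentiation genes moved in both directions. Among granulocyte and granule genes, 8 of 15 fell and 5 rose (camera, lower, adjusted p = 1.17e-04, and adjusted p = 0.335 with an estimated correlation; 0.059 with limma-voom). The myeloperoxidase gene MPO fell 27.5-fold, from 6.12 ± 0.505 to 0.217 ± 0.00507 CPM. PRTN3 and CTSG, which with ELANE encode serine proteases of primary granules, fell 5.98-fold and 6.81-fold. The abundant list member AZU1 did not fall, going from 751 ± 8.61 to 825 ± 33.2 CPM (log2 fold change 0.14). The gelatinase gene MMP9 rose 76.3-fold to 6.51 ± 0.674 CPM. Of 26 monocyte and macrophage genes, 15 rose and 9 fell, and the list did not pass (camera adjusted p = 0.053, and adjusted p = 0.414 with an estimated correlation). It passed when any 1 of the 4 libraries was left out, with adjusted p between 0.0116 and 0.0449. The integrin gene ITGAX (CD11c) rose 19.2-fold and the co-stimulatory ligand CD80 14.1-fold, the latter at a low level, from 5 to 68 reads. FCN1 had 2 and 146 reads, a ratio of 79.3 (95% interval 21.6 to 661). S100A8, S100A9 and LYZ, abundant in classical monocytes, fell by 1.95, 1.11 and 0.65 on the log2 scale. The co-stimulatory ligand CD86 fell by 1.57, also at a low level (1.04 ± 0.0514 to 0.344 ± 0.299 CPM).

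The stem cell and MLL-fusion list did not pass (13 of 19 rose, 5 fell, camera adjusted p = 0.206), and its changes were small. It passed without the first or the second CU-T12-9 library (adjusted p = 0.0234 and 0.0406). HOXA9, HOXA10 and MEIS1, kept active by MLL fusions, rose by 0.43, 0.48 and 0.46 on the log2 scale. KIT, SOX4 and IGF2BP2 rose 1.92-fold, 1.75-fold and 1.66-fold, and BCL2 fell 1.63-fold. The FLT3 and STAT5 list did not pass either (6 of 13 rose and 5 fell, 7 and 5 adjusted over the list alone, camera adjusted p = 0.781). Its median was 0.19 and its mean -0.18, and camera gave the lower direction. Beside OSM, the kinase gene PIM1 fell 3.77-fold, while SOCS3 and STAT5A rose 3.07-fold and 2.31-fold. FLT3 itself fell by 0.31 on the log2 scale.

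The p53 target list was higher, with 16 of 22 genes up and 3 down (camera adjusted p = 0.00109, and adjusted p = 0.335 with an estimated correlation). The antiproliferative gene BTG2 rose 5.23-fold, TP53INP1 4.8-fold, ZMAT3 3-fold and the cell cycle inhibitor CDKN1A 2.24-fold, from 108 ± 2.23 to 241 ± 15 CPM. In the BCL2 family and caspase list 12 of 21 genes rose and 5 fell (camera, higher, adjusted p = 0.0442, and adjusted p = 0.421 with an estimated correlation). Its adjusted p was 0.0547 with a filter of 1 CPM and 0.05 with limma-voom, neither under the threshold. Anti-apoptotic BCL2A1 rose 27.7-fold, from 0.179 ± 0.0176 CPM, and the pro-apoptotic BMF and BCL2L11 (BIM) rose 6.68-fold and 2.29-fold, with CASP1 at 2.08-fold.

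All 16 NRF2 and AHR response genes rose, with a median log2 fold change of 1.57 (camera adjusted p = 2.52e-14, and adjusted p = 0.246 with an estimated correlation). The cystine transporter gene SLC7A11 rose 33.6-fold to 174 ± 8 CPM, CYP1B1 8.69-fold, HMOX1 8.39-fold and OSGIN1 8.33-fold. Of 18 lysosome and autophagy genes, 13 rose and 1 fell (camera adjusted p = 9.66e-04, and adjusted p = 0.414 with an estimated correlation). GABARAPL1, SQSTM1 and LAMP1 rose 4.77-fold, 4.13-fold and 2.13-fold, while CTSL fell from 1.16 ± 0.0124 to 0.434 ± 0.0514 CPM, a call that DESeq2 did not make (adjusted p = 0.0558).

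Of the MAPK immediate early and feedback genes 10 of 25 rose and 7 fell (10 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.11). EGR2, EGR3, DUSP4 and IER3 rose 21.6-fold, 10.6-fold, 7.44-fold and 6.65-fold, EGR2 from only 5 reads to 104. The unfolded protein and ATF4 list did not pass (5 of 21 rose and 13 fell, 5 and 14 adjusted over the list alone, camera adjusted p = 0.212). It passed without the second DMSO library (adjusted p = 0.0492) and without the second CU-T12-9 library (adjusted p = 0.0382). SLC7A11 and CHAC1 (10.1-fold) rose, and the serine synthesis genes PHGDH and PSAT1 fell 2.78-fold and 2.18-fold. Cholesterol synthesis (4 of 16 up, 8 down, camera adjusted p = 0.206) did not pass either, though it did with no filter on low counts (adjusted p = 0.0359) and by fry (adjusted p = 0.0256). Its genes FDPS, IDI1 and SQLE fell 1.59-fold, 1.58-fold and 1.42-fold. Hypoxia and glycolysis genes went both ways, 6 of 18 up and 5 down (camera adjusted p = 0.885), with a median of -0.01 and a mean of 0.10. LDHA fell 2.43-fold, and BNIP3L, VEGFA and HK2 rose 2.87-fold, 2.28-fold and 2.25-fold. Of 13 mitochondrially encoded mRNAs 8 rose and 1 fell, and the list did not pass (camera adjusted p = 0.304). It passed without the first DMSO library (adjusted p = 0.0235) or without the first CU-T12-9 library (adjusted p = 0.0361). MT-ND1, MT-CO1 and MT-ND5 rose 1.44-fold, 1.42-fold and 1.39-fold. MT-ND6, encoded on the other strand, fell by 0.61 on the log2 scale, a call that DESeq2 did not make (adjusted p = 0.199). All mitochondrially encoded rows together, ribosomal and transfer RNA included, took 2.27% and 1.95% of DMSO reads and 2.65% and 2.71% of CU-T12-9 reads.

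Markers of other cell types were mostly too low to test. Of the T and NK markers 3 were tested, of which IL7R (5.08-fold) and NKG7 (1.97-fold) rose. Both tested B cell markers rose from low levels, CD22 from 3 to 39 reads and PAX5 from 0.537 ± 0.11 to 1.11 ± 0.0049 CPM, the latter not called by DESeq2 (adjusted p = 0.146) nor without either DMSO library (edgeR adjusted p = 0.0632 and 0.186). Of 2 erythroid markers EPOR fell 2.09-fold. Of 3 megakaryocyte markers, GP1BA rose from 1 to 201 reads, a ratio of 218 (95% interval 38.8 to 8670), and ITGA2B fell by 0.38 on the log2 scale, which was not called by DESeq2 (adjusted p = 0.186) nor without either DMSO library or the first CU-T12-9 library (edgeR adjusted p 0.101 to 0.175). Of 4 epithelial and fibroblast markers KRT18 fell 2.26-fold, DCN had 0 reads under DMSO and 36 under CU-T12-9 (at least 13-fold higher), and LUM had 1 and 28 (ratio 30.4, 95% interval 5.03 to 1244).

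**Figure D3:**
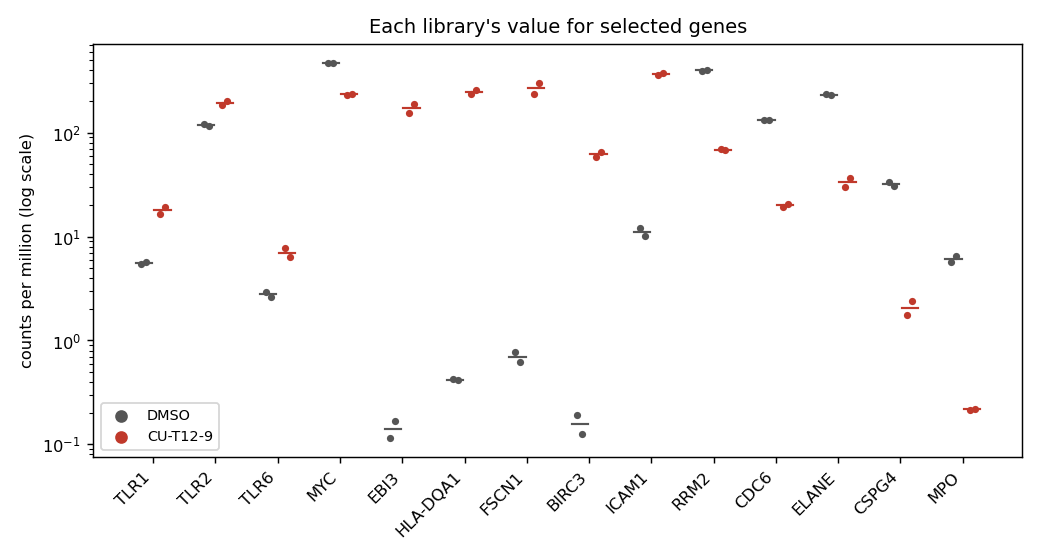
Level of 14 genes named in the text in each of the 4 libraries, in CPM on a log axis, with a bar at the mean of each group of 2. The groups do not overlap for any of the genes shown, and TLR1 goes from 5.61 to 18 CPM while MYC goes from 471 to 233 CPM.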

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

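Thinning the libraries and the test against a fold of 2 were chosen only after the result was seen. None of the 9135 changed genes changed sign in any setting. The count of changed genes stayed within 1.5 times, from 6555 against a fold of 1.2 (glmTreat) to 9908 without the second CU-T12-9 library, except that 1791 genes, 1013 higher and 778 lower, passed against a fold of 2. This setting asks for larger changes by construction. DESeq2 called 7574 genes, 7571 of them among the 9135. Leaving out each library in turn, with the lone library assumed to vary like the other group, gave 7615 to 9908 genes, and another scaling moved the median of all genes by between -0.0154 and 0.0132 on the log2 scale. Every scaling used here is relative to the reads of a library, so a change in RNA per cell would not be seen. The direction of small list medians rests on these scalings. With the replicate number as a block 9143 genes were called, 8972 of them among the 9135, and the monocyte list passed (adjusted p = 0.0242). The numbers were not taken to pair the samples: differences between replicates 1 and 2 correlated at 0.00795 between the groups, and the labels name no shared day. Of the 14 lists called by camera, 2 were called with an estimated correlation, a setting that rests on 2 residual degrees of freedom. Of all 22 lists fry called 19. Lists that did not pass gained a call in some settings: monocyte genes with library totals alone (adjusted p = 0.0418) or no filter (0.0233), unfolded protein genes with no filter (0.0144) or limma-voom (0.0477), stem cell genes with limma-voom (0.0464) and cholesterol synthesis with no filter (0.0359). Among single named genes, only CTSL, PAX5, ITGA2B and MT-ND6 lost their call in DESeq2, and PAX5 and ITGA2B also without single libraries (adjusted p 0.0632 and 0.186 for PAX5 without the first or second DMSO library; 0.101 to 0.175 for ITGA2B without either DMSO library or the first CU-T12-9 library). The cause was not tested. Depth limits genes with few reads, such as CD14, IL1A and GBP1, which the expression filter removed.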

Other observations

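The gene lists and genes of this part, the thinning of the libraries, and the tests for fibroblast transcripts and for another cell line were chosen only after the result was seen. Complement and chemoattractant receptor genes were among the large rises. C3, the central complement component, rose from 3.64 ± 0.527 to 576 ± 32.4 CPM (SD, n = 2) and C1QB had 0 and 125 reads (at least 45.3-fold higher). Of 12 tested complement genes 7 rose and 4 fell (camera adjusted p = 9.94e-05 over 7 such lists, and adjusted p = 0.236 with an estimated correlation). Of 14 receptors for chemokines and chemoattractants 11 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 7.61e-08, and adjusted p = 0.236 with an estimated correlation), among them PTAFR from 11.2 to 332 CPM, CMKLR1 from 0.369 to 15.1 CPM and FPR1 from 0.221 to 6.24 CPM. Of 17 surface antigens and checkpoint ligands of interest in acute myeloid leukaemia 9 rose and 6 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.00189, and adjusted p = 0.236 with an estimated correlation). The ligand gene CD274 (PD-L1) went from 3 to 349 reads, a ratio of 126 (95% interval 42.9 to 616), PDCD1LG2 from 4 to 340 reads, and CD44 and CD70 rose by 1.91 and 2.57 on the log2 scale. CLEC12A fell by 3.61 and CD33 by 0.41.

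Both ferritin chain genes were abundant and rose. FTH1, the ferritin heavy chain, rose 22.8-fold from 356 ± 12.4 to 8099 ± 390 CPM, and FTL 3.04-fold from 4717 ± 78.5 to 14349 ± 1107 CPM. FTH1P3, the one ferritin pseudogene row with at least 20 reads in all, had 9 reads under DMSO and 13 under CU-T12-9. The iron exporter SLC40A1 fell by 2.43 on the log2 scale, while the transferrin receptor TFRC, at -0.02, did not pass. Of 14 iron genes 7 rose and 5 fell (camera adjusted p = 0.0259, and adjusted p = 0.309 with an estimated correlation). All 16 Fanconi and homologous recombination genes fell, with a median of -2.07 (camera adjusted p = 6.6e-20, and adjusted p = 0.0685 with an estimated correlation). BRCA1 fell by 1.94 on the log2 scale. Of 22 nuclear-encoded genes of oxidative phosphorylation 18 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0152, and adjusted p = 0.236 with an estimated correlation), while 8 of the 13 mitochondrially encoded mRNAs rose.

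Several genes outside the naming rule were singled out after their values were seen. IGLL1, a surrogate light chain gene, had 100 reads under DMSO and 0 under CU-T12-9, at least 30.7-fold lower. The MIR146A gene row, which does not count mature microRNA arms, had 4 and 1433 reads. MIR155HG, the host gene of another NF-kB-induced microRNA, did not pass (log2 fold change -0.09, SE 0.14), nor did IRF1 (-0.06, SE 0.07). The 19 rows of interferon genes themselves, IFNB1 included, held 1 read under DMSO and 3 under CU-T12-9 at 24 h, so a difference in them was not detectable at this depth.

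Histone transcripts rose (16 of 22 tested replication-dependent histone genes) while all 31 cell cycle genes fell. More RNA without a poly(A) tail in the CU-T12-9 libraries would raise other such RNAs by about as much, but 8 rows of 7SK, 7SL, small nuclear and related RNAs had a median log2 change of 0.485 (95% bootstrap interval 0.0719 to 0.748), which argues against it as the whole cause and leaves a smaller part open. Reads moved between near-identical histone rows cannot raise their sum, and the log2 ratio of the summed CPM of all 88 histone rows was 1.74. The handling of reads that map to several places is not known. If they were discarded, a shift toward rows of more distinct sequence could raise the sum, and the sum does not address that case. Of the gain in this sum 89.5% lay in HIST1H2BK, HIST1H2AC, HIST2H2BE, HIST1H1C and HIST1H2BD, while the rows too low to test had 168 reads under DMSO and 152 under CU-T12-9. A candidate explanation is polyadenylated histone transcripts made in cells that leave the cycle, which was not tested.

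DCN, LUM, COL6A1 and COL6A2, genes of connective tissue cells, were higher under CU-T12-9, with COL6A1 going from 14.1 ± 0.696 to 608 ± 45.9 CPM. Fibroblasts in the cultures would bring their abundant collagen I and III transcripts. In the CU-T12-9 libraries COL1A1, COL1A2 and COL3A1 together reached at most 0.000572 of the summed CPM of COL6A1 and COL6A2. This argues against fibroblasts as the source of COL6A1 and COL6A2. DCN and LUM stayed low under CU-T12-9 (means of 0.781 and 0.612 CPM), and COL1A1 had 6 and 1 reads there. The ratio therefore does not bear on the source of DCN and LUM, which stays open. COL6A3, the third chain of collagen VI, stayed low, with 15 reads under DMSO and 20 under CU-T12-9. Expression by the leukaemia cells themselves may account for the rise of COL6A1 and COL6A2, as a hypothesis found and tested on the same data.

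Most of the tested genes (65.2%) changed; with another cell line in place of MV4;11 in the CU-T12-9 dishes, many genes expressed under DMSO would be missing, but 0 of the 9950 genes at 5 CPM or more under DMSO had 3 or fewer reads over both CU-T12-9 libraries, and none of HOXA9, HOXA10, MEIS1, PBX3 and MEF2C moved by more than 0.48 on the log2 scale. In the other direction 13 of 10132 genes at 5 CPM or more under CU-T12-9 had 3 or fewer reads over both DMSO libraries. A second line mixed with MV4;11 lowers genes only by dilution, which can leave them above 3 reads. These counts therefore do not address a mixture. The fall of IGLL1, at least 30.7-fold, would need MV4;11 to be nearly replaced if dilution were its only cause. IGLL1 is a single gene, at 1.995 CPM under DMSO and picked after its value was seen. Better counted genes also fell far, among them CSPG4 (15.6-fold) and SLC38A5 (11.9-fold). In all, 9 genes fell and 199 rose by a fitted fold over 16. These are the largest falls, and a response of MV4;11 could add to dilution, so a mixture stays open. The slightly deeper DMSO libraries are argued against, since 9066 genes changed after each library was thinned to the smallest total. A response to CU-T12-9 may underlie the breadth of the change, but a difference between the dishes in vehicle, density or handling was not tested and is confounded with the treatment in this design.

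CCR7, FSCN1 and EBI3 among the largest rises, with CD40 and class II genes, led to the hypothesis that a dendritic cell maturation programme rose as a group. The co-stimulatory ligands CD80 and CD86, outside the tested list, went opposite ways at low levels, by 3.82 and -1.57 on the log2 scale. The hypothesis was tested on list members other than the genes that led to it, in the same data. CD274 and PDCD1LG2 among these list members are also members of the surface antigen list above. The median log2 change of the list was 1.68 over 12 tested genes, of which 7 rose and 3 fell. The camera adjusted p over the 7 lists of this part was 9.94e-05, and 0.236 with an estimated correlation. LAMP3 went from 1 to 270 reads, a ratio of 293 (95% interval 52.2 to 11631), CCL19 from 0 to 90 reads (at least 32.6-fold higher) and DAPP1 rose by 3.33 on the log2 scale, while TBC1D4, CRIP1 and KIF2A fell by 1.66, 0.89 and 0.54. The values are consistent with such a programme in part, but CD274 and other members are also induced by NF-kB and interferon, so the list does not separate the possibilities.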
